A study of Mus musculus with 15 samples.

How the data were processed

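RNA sequencing of mouse lung was deposited for 15 libraries, 5 from control mice, 5 from mice sensitised and challenged with ovalbumin (OVA) and 5 from OVA mice that also received ginsenoside Rg3 (OVA_Rg3). The replicates are biological replicates, per the labels. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was enriched with oligo(dT) beads and libraries were made with the TruSeq RNA kit, all in batch 1.

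The deposited values are taken to be FPKM, that is, reads scaled by gene length and by the number of reads of the library. The file header names no unit, and this reading was inferred from the values. TPM calculated over a larger set of genes could not be excluded. The submitters' processing notes name Trimmomatic, featureCounts and the builds GRCm39 and mm39, with no versions. Positions in the deposited table matched those of GRCm38, since 13555 of the 14766 genes had the same coordinates in GENCODE release M21 of that build, so coordinates below are those of the deposited table on GRCm38. The table holds 14766 protein-coding genes, and 14756 of their identifiers were found in that annotation.

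Read counts were not used here. In each library the low values of genes with a single transcript (1776 genes) were searched for the step that 1 read makes. Between 34.6% and 51.3% of the low values lay within 2% of whole steps, against 8% by chance. If the values are FPKM, these steps imply 0.216 to 8.98 M reads per library, a 41.6-fold range. A value of 3 reads on a transcript of 1 kb was 0.334 in control 1, 3.62 in control 2 and 13.9 in OVA_Rg3 1, and these floors cover counting error only.

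Values were analysed as log2(value + 1). Genes with a value of at least 1 in at least 5 libraries were tested (12137 genes) with limma 3.58.1 in R 4.3.3. The model had 1 mean per group over all 15 libraries, with a mean-variance trend and robust estimation, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The planned count model could not be used, because the file holds no counts, and the planned model for normalised values was used in its place. The 3 comparisons were OVA against control, OVA_Rg3 against OVA and OVA_Rg3 against control. Genes changed by OVA and changed back by Rg3 were counted where both calls had opposite signs. Figures and summaries of libraries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

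Groups of genes were tested with 43 lists written before the data were examined. They covered type 2 cytokines and chemokines, alternatively activated macrophages, mucous cells, eosinophils, mast cells and basophils, T helper 2 and regulatory T cells, T cells, natural killer cells, B cells, plasma cells, germinal centre, neutrophils, proinflammatory cytokines, NF-kappaB, interferon-stimulated genes, MHC class II, dendritic cells, monocytes and interstitial macrophages, and alveolar macrophages. They also covered leukotriene and prostaglandin synthesis, cell cycle, extracellular matrix, smooth muscle, alveolar type 1 and type 2 cells, club cells, ciliated cells, endothelium, Nrf2, aryl hydrocarbon receptor, glucocorticoid response, circadian clock, immediate early genes, heat shock and mitochondrially encoded transcripts. The last lists were markers of cardiac and skeletal muscle, adipose tissue, thymus, squamous epithelium, mesothelium, blood and sex. Camera (limma) with a preset correlation of 0.01 tested the 37 lists with at least 3 tested genes against all other genes. Camera with an estimated correlation and fry were also run, with Benjamini-Hochberg adjustment over the lists, and members were adjusted over the list alone as well. Mean log2 values of each list per library were compared with exact two-sided permutation tests, 5 libraries against 5.

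Named genes followed a rule fixed before the data were examined. It took, per comparison, up to 10 risen and 10 fallen genes of largest log2 change among called genes whose 5 libraries of one group all lay above the 5 of the other, with a mean of at least 1. It also took up to 4 genes of smallest p from each list, 16 fixed genes of allergic inflammation, up to 10 genes changed back, and the 5 genes of smallest p where no gene was called. Numbered gene models and variable segments were left out. The rule named 166, 158 and 171 genes in the 3 comparisons in the order above, and all of them entered the alternatives. The report prints the genes of largest change, the fixed genes, the genes of smallest p, and the first 2 members by p of each list past the threshold of camera or of the exact test of list means, with 1 gene left out.

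Alternatives fixed before the data were examined were quantile normalization, no filter, a filter of at least 5 in 5 libraries, array weights, a fit of only the groups compared, the replicate number as a block, a threshold of log2 1, a pseudocount of 0.1, an estimated correlation in camera, and each library left out in turn. Alternatives chosen after seeing the data were median-ratio scaling over the 6365 genes at 1 or more in every library, a fit without control 2, OVA 4 and OVA_Rg3 1, which held transcripts of several other organs, and both together. OVA_Rg3 5, with liver transcripts, stayed in those fits. Median-ratio scaling moved the median log2 change of all tested genes from -0.73 to -0.09 in OVA against control, from 0.32 to 0.02 in OVA_Rg3 against OVA, and from -0.43 to -0.08 in OVA_Rg3 against control. "Scaled" below means after this scaling.

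Simulated data were made from median-ratio scaled values, with the deviations of the libraries shuffled, so they lack most shifts of whole libraries. Rates found in them need not hold for the deposited values. The test was tried on these data with 200 of 12137 genes changed, in 10 draws. In OVA against control it recovered 41.6% of genes changed by log2 1 and 91.2% of those changed by log2 2, and 2.85% of calls were false. In OVA_Rg3 against OVA the shares were 44.1% and 88.8% with 1.34% false, and in OVA_Rg3 against control 44.9% and 90.6% with 5.51% false. Camera was tried on lists of 10 genes drawn at random, some of them raised by log2 2. It found 100% of the raised lists in each comparison, which does not show its power for smaller changes. It called 0% of the unchanged lists in OVA against control, 1.14% in OVA_Rg3 against OVA and 0.857% in OVA_Rg3 against control. Random genes do not vary together as markers of a cell type can, so these shares need not hold for the real lists.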

Results

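Gene expression was measured by RNA sequencing in lung tissue of wild-type mice in 3 groups of 5. Control mice received saline. OVA mice were sensitised by intraperitoneal injection and challenged by aerosol with ovalbumin, an egg protein that causes allergic airway inflammation. OVA_Rg3 mice had the same induction and were given 20 mg/kg of ginsenoside Rg3, a saponin of ginseng, by gavage. Read counts were not used here. The values imply 8.98, 0.829, 6.61, 7.55 and 6.20 M reads for controls 1 to 5, 2.81, 3.45, 2.99, 3.63 and 3.15 M for OVA 1 to 5, and 0.216, 3.87, 3.43, 1.60 and 2.37 M for OVA_Rg3 1 to 5. Low values of control 2 and OVA_Rg3 1 are therefore coarse. A gene listed at 0 there may be absent or may have been missed at this depth.

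Mitochondrially encoded transcripts took 24.6% ± 3.95 (SD, n = 5) of the summed values in control lungs, 65.0% ± 15.9 (SD, n = 5) in OVA lungs and 56.4% ± 10.3 (SD, n = 5) in OVA_Rg3 lungs. The share was higher in all 5 OVA and all 5 OVA_Rg3 libraries than in any control (exact permutation test, two-sided, p = 0.00794 each, adjusted p = 0.0119 over 6 tests). OVA_Rg3 and OVA overlapped (exact permutation p = 0.349, two-sided). Scgb1a1, the secretoglobin of club cells, took 23.5% ± 9.28 (SD, n = 5) in control, 5.72% ± 4.32 (SD, n = 5) in OVA and 6.03% ± 1.72 (SD, n = 5) in OVA_Rg3. Both differences from control had an exact permutation p of 0.00794 (two-sided), the smallest that 5 against 5 can give, and OVA_Rg3 against OVA had p = 0.913. Because shares of this size lower the values of all other genes, all comparisons were repeated after median-ratio scaling. Values are as deposited unless scaling is named.

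**Figure D1:**
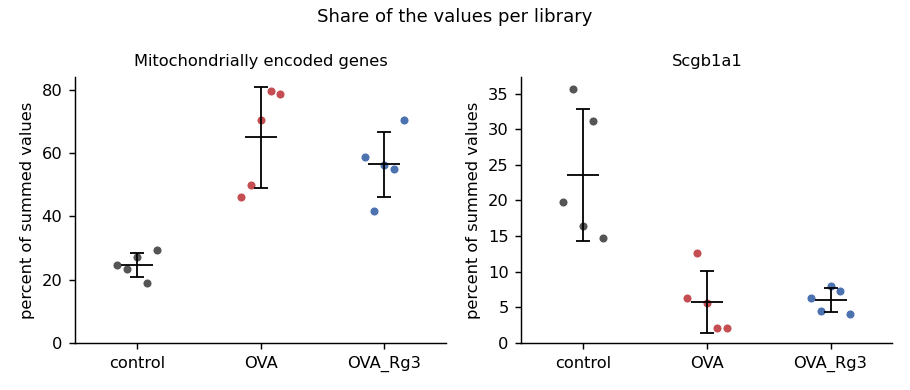
Percent of the summed values (y axis) from mitochondrially encoded transcripts and from Scgb1a1 in control, OVA and OVA_Rg3 lungs. Dots are libraries, and bars are means ± SD of 5 libraries. The mitochondrial share lies at 18.9% to 29.3% in control and at 46.2% to 79.8% in OVA.

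The comparison of OVA with control asks what the allergic airway model changed in the lung. Some macrophage genes were higher with OVA and others lower. Chil3, a chitinase-like protein, was 563 ± 638 in OVA and 32.4 ± 11.3 in control (SD, n = 5 each). Arg1, arginase 1, was 23.4 ± 23.4 against 1.82 ± 2.90 (SD, n = 5 each). Control 2, with liver transcripts, had Arg1 at 7.00 (other controls at most 0.876). Most club and ciliated cell genes were lower. Cyp2f2, a club cell cytochrome P450, was 452 ± 286 (SD, n = 5) against 2861 ± 752 (SD, n = 5). Foxj1, the transcription factor of ciliated cells, was 23.8 ± 16.2 (SD, n = 5) against 150 ± 53.3 (SD, n = 5). Acta2, the actin of smooth muscle, was 21.1 ± 3.24 (SD, n = 5) against 204 ± 44.0 (SD, n = 5).

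Of 12137 genes tested with limma, 70 rose and 6216 fell with OVA, so 98.9% of the calls were lower. After median-ratio scaling 655 rose and 1278 fell, or 66.1% lower, and quantile normalization gave 921 higher and 1085 lower. All 1278 genes that fell after scaling and 69 of the 655 that rose had been called in the same direction in the deposited values. The libraries of the 2 groups did not overlap for 34 genes higher and 3891 lower in OVA, 32.3% of the genes tested, against 0.794% by chance. This was counted in the deposited values only, where the median log2 change was -0.73. Without control 2, OVA 4 and OVA_Rg3 1, which held transcripts of other organs, 103 genes rose and 6401 fell, and 961 rose and 1592 fell after scaling. Array weights gave 10020 genes, the filter at a value of 5 gave 3836, and a minimum log2 change of 1 gave 3376. After scaling the count was 1231 without control 1, 1141 without control 3, 1175 without control 4 and 1261 without OVA 5.

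The largest rise among genes whose groups did not overlap was that of Mmp12, macrophage metalloelastase (ENSMUSG00000049723.14, chromosome 9, 7344381 to 7369499), by log2 4.11 ± 0.79 (SE, n = 5 per group; limma adjusted p = 0.000920). It ranged from 10.05 to 238 in OVA and from 0.434 to 3.53 in control. Chil3 (ENSMUSG00000040809.10, chromosome 3, 106147554 to 106167564) rose by 3.38 ± 0.65 (SE) and Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484) by 3.13 ± 0.61 (SE), with limma adjusted p of 0.000956 and 0.00102. Chil3 has a near-identical relative, Chil4, and reads may be split between them. Rnase2a, an eosinophil-associated ribonuclease, rose by 2.93, Atp6v0d2, a subunit of the vacuolar proton pump, by 2.19 and Bex1 by 1.73, while mt-Co2, mt-Nd3, mt-Co3 and mt-Cytb of the respiratory chain rose by 1.88, 1.84, 1.83 and 1.65. All 10 also rose after scaling, by 2.45 (Bex1) to 4.67 (Mmp12). Quantile normalization ended the calls of mt-Co3 (limma adjusted p = 0.102) and mt-Cytb (limma adjusted p = 0.638). It gives all libraries the same set of values, which holds down rises among the most abundant genes, such as these. Bex1 lost its call without control 3, 4 or 5 (limma adjusted p = 0.0505, 0.0547 and 0.0615) or OVA 1 or 5 (0.0723 and 0.0532).

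The largest fall was that of Pon1, paraoxonase 1 (ENSMUSG00000002588.12, chromosome 6, 5168090 to 5193946), by 4.10 ± 0.30 (SE) on the log2 scale, with 2.62 ± 0.852 (SD, n = 5) in OVA and 61.8 ± 18.8 (SD, n = 5) in control (limma adjusted p = 1.03e-06). Scgb1c1 fell by 3.71, Cckar, the cholecystokinin A receptor, by 3.57, Sult1d1, a sulfotransferase, by 3.51 and Cnn1, calponin of smooth muscle, by 3.35. Slc25a36, a mitochondrial carrier, fell by 3.31, Actg2, the enteric smooth muscle actin, by 3.28, Cyp2a5, a cytochrome P450, by 3.28, Cxcl17, a mucosal chemokine, by 3.26 and Nme9 by 3.26. All 10 also fell after scaling, by 2.42 (Cyp2a5) to 3.32 (Pon1) on the log2 scale. Scgb1c1 ranged from 0.609 to 9.34 in OVA and from 44.4 to 111 in control, and Cnn1 from 1.31 to 7.82 and from 39.0 to 66.0. Both were listed at 0 in OVA_Rg3 1.

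**Figure D2:**
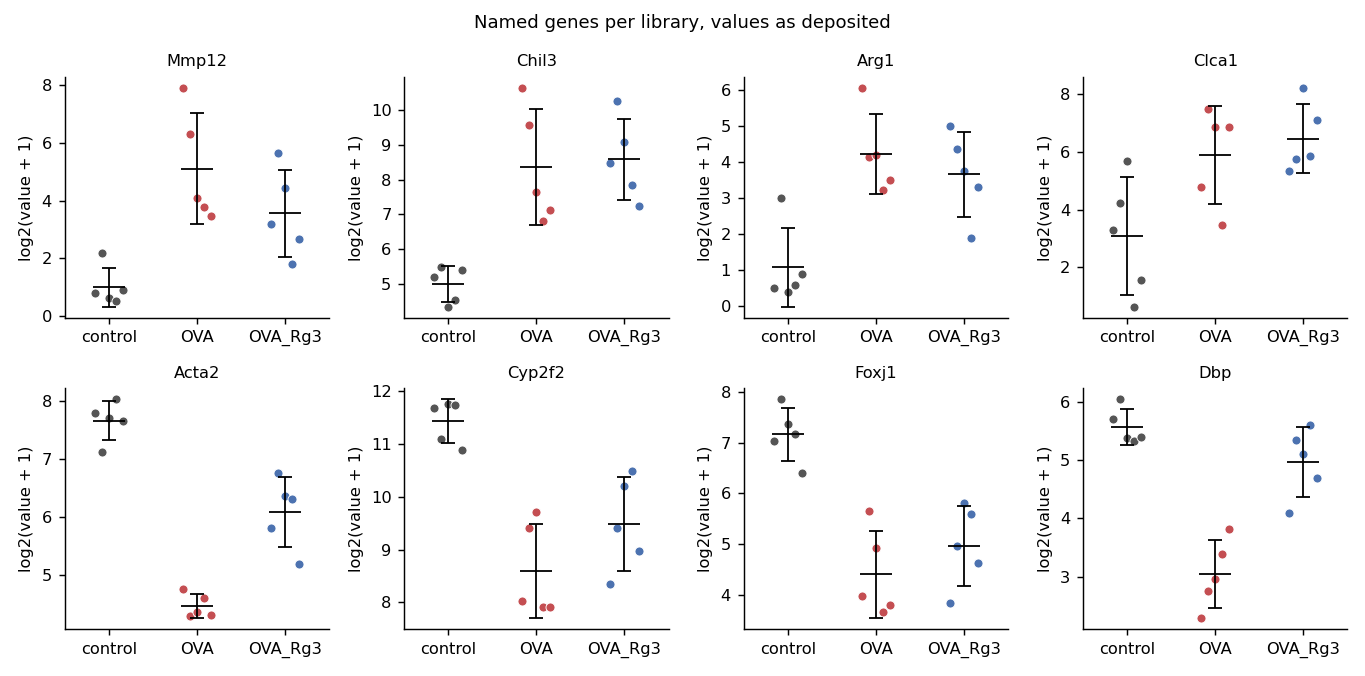
Values of 8 genes on a log axis in control, OVA and OVA_Rg3 lungs. Dots are libraries, and bars are means ± SD of 5 libraries. Chil3 lies at 19.2 to 44.0 in control and at 111 to 1597 in OVA.

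All 8 smooth muscle genes fell with OVA, with a median of -2.63 (camera adjusted p = 1.3e-07), and all 8 fell after scaling, with a median of -1.82. The call was lost with an estimated correlation (adjusted p = 0.157 with an estimated correlation). Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255336) fell by 3.20 ± 0.26 (SE) on the log2 scale, and Actg2 fell by 3.28 ± 0.34 (SE). Of 7 club cell genes 6 fell (median -2.10, camera adjusted p = 0.00312; adjusted p = 0.418 with an estimated correlation), and 4 fell after scaling. Cbr2, a carbonyl reductase, fell by 2.28 and Cyp2f2 by 2.84. All 9 ciliated cell genes fell (median -2.45, camera adjusted p = 0.000398; adjusted p = 0.429 with an estimated correlation), and 6 fell after scaling. Tppp3, a tubulin-binding protein, fell by 2.38 and Foxj1 by 2.75. Adjusted over the list alone, the counts were 8, 6 and 9. The mitochondrial share was higher in the same OVA libraries.

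List means per library gave exact permutation tests (two-sided) of p = 0.00794, adjusted p = 0.0489, for 6 lists, with all 5 OVA libraries beyond all 5 controls. These were the lists of smooth muscle, club cells, ciliated cells, mitochondrial transcripts, the circadian clock and Nrf2. After median-ratio scaling 6 passed, with alternatively activated macrophages (difference 1.11) and erythroid genes (1.96) in place of club cells (adjusted p = 0.0801) and Nrf2 (adjusted p = 0.137). As deposited, none of the 37 lists passed without control 1, 2, 3 or 4 or OVA 4 or 5. With all libraries, 6 lists had to reach the smallest p for any to pass, and 6 did. Losing a list from it can thus end all 6 calls, so this loss says little about single lists. Of 14 clock genes 8 fell, or 9 adjusted over the list alone, with a median of -1.15 (camera adjusted p = 0.199), and 5 fell after scaling. Dbp, an output gene of the clock, fell by 2.53 and Per3, a period protein, by 1.82. Of 7 Nrf2 antioxidant genes 5 fell, also adjusted over the list alone (median -1.37, camera adjusted p = 0.540). Nqo1, a quinone reductase, fell by 2.17, and Gclm, of glutathione synthesis, fell by 1.37 as deposited, with -0.71 after scaling (limma adjusted p = 0.116).

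**Figure D3:**
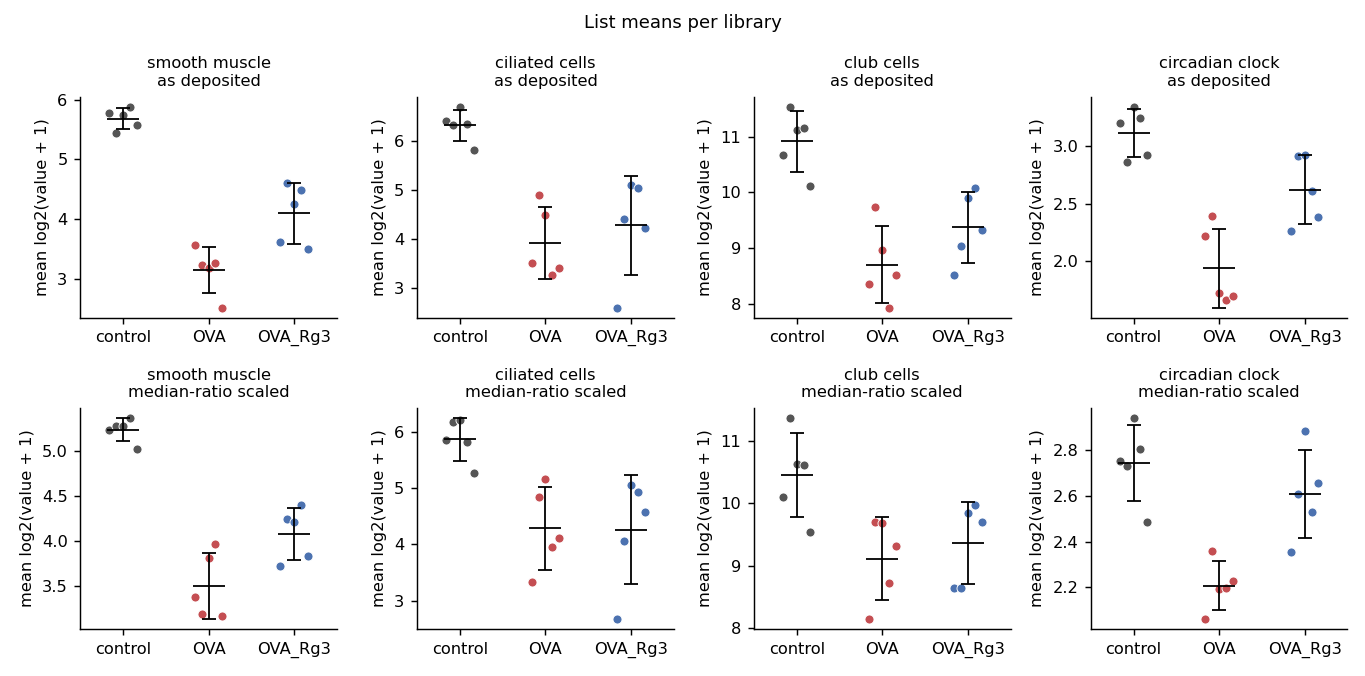
Mean log2(value + 1) of the smooth muscle, ciliated, club and circadian lists per library, as deposited and after median-ratio scaling. Dots are libraries, and bars are means ± SD of 5 libraries. As deposited, the smooth muscle mean is 5.68 in control, 3.15 in OVA and 4.10 in OVA_Rg3.

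All 9 mitochondrially encoded genes rose (median 1.56, camera adjusted p = 5.08e-36; adjusted p = 0.00977 with an estimated correlation). After scaling the median was 2.44 and the estimated correlation gave adjusted p = 0.288. mt-Co1 rose by 1.60 and mt-Co2 by 1.88. With quantile normalization the camera call of the list was lost (median 0.20, adjusted p = 0.373). That method holds down rises among the most abundant genes, so this loss says little about the list. Of 6 erythroid genes of blood 4 rose, or 6 adjusted over the list alone (median 1.29, camera adjusted p = 1.03e-16; adjusted p = 0.0473 with an estimated correlation and 0.288 after scaling as well), and 6 rose after scaling. Hbb-bs and Hba-a1, globins, rose by 1.33 and 1.31.

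Camera compares a list with all other genes, whose median here was -0.73, and 12 further lists passed as higher than those. After scaling camera called 9 lists up and 4 down, and with quantile normalization 6 up and 4 down, against 14 up and 3 down as deposited. Of 10 genes of alternatively activated macrophages 3 rose and 3 fell, also adjusted over the list alone, with a median of -0.33 and a mean of 0.55 (camera up, adjusted p = 5.06e-05; adjusted p = 0.157 with an estimated correlation), and the call was lost after scaling (adjusted p = 0.0969) and with quantile normalization. Of 8 plasma cell genes 2 rose and 2 fell, also over the list alone (median 0.72, camera up, adjusted p = 1.3e-07; adjusted p = 0.157 with an estimated correlation). Jchain, the joining chain of secreted antibodies, rose by 3.65 ± 0.91 (SE) and Sdc1, syndecan 1, fell by 1.84. None of 6 B cell genes passed, also adjusted over the list alone, and 2 rose after scaling (median 0.53, camera up, adjusted p = 3.63e-07; adjusted p = 0.157 with an estimated correlation). Pax5 and Cd79a, B cell identity genes, had log2 changes of 0.54 and 0.91. None of 8 type 2 cytokine and chemokine genes passed, also over the list alone, and 4 rose after scaling (median 0.16, camera up, adjusted p = 2.11e-05; adjusted p = 0.218 with an estimated correlation). The call was lost with scaling and without the 3 libraries (adjusted p = 0.0537). Ccl8, a chemokine, had a log2 change of 1.09 (limma adjusted p = 0.0670), and Ccl7 had -1.01, with OVA 5 at 0 and values up to 18.2 in control and up to 2.10 in OVA.

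Of 10 mucous cell genes 2 rose and 2 fell, and 0 passed adjusted over the list alone, and 1 rose after scaling. The median was -0.07 and the mean -0.10, while camera ranked the list up (adjusted p = 0.000151; adjusted p = 0.249 with an estimated correlation). The call was lost after scaling (adjusted p = 0.167) and with quantile normalization. Clca1, a secreted protein of mucous cells, rose by 2.81 ± 0.90 (SE, limma adjusted p = 0.0182) and lost its call without control 4 or 5 or OVA 5 (limma adjusted p = 0.0524, 0.0514 and 0.0503) and with array weights. Agr2, a chaperone of mucin folding, fell by 1.56, with 0.669 to 7.12 in OVA and 5.08 to 28.1 in control, and lost its call without control 3 or OVA 3 or 4 (limma adjusted p = 0.0760, 0.0539 and 0.0777), with scaling (limma adjusted p = 0.326) and with quantile normalization.

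Of 7 alveolar macrophage genes 2 rose and 2 fell, also adjusted over the list alone, with a median of 0.13 and a mean of -0.13 (camera up, adjusted p = 0.00103; adjusted p = 0.157 with an estimated correlation). The call was kept after scaling (adjusted p = 0.0475) and lost with quantile normalization and with scaling and without the 3 libraries (adjusted p = 0.146 for the latter). Plet1, a surface protein, fell by 2.26 and Atp6v0d2 rose by 2.19. Of 8 proinflammatory genes 1 rose and 2 fell, or 1 and 1 over the list alone, with a median of -0.58 and a mean of -0.38 (camera up, adjusted p = 0.0265; adjusted p = 0.429 with an estimated correlation). This call was lost after scaling (camera adjusted p = 0.387), with quantile normalization, and without control 3 or 4 or OVA 5 (camera adjusted p = 0.0688, 0.0998 and 0.0579). Ptgs2, cyclooxygenase 2, fell by 1.66, and Ccl3, a chemokine, rose by 1.43, from 0 to 2.35 in control to 1.08 to 7.18 in OVA. Of 10 immediate early genes 1 rose and 3 fell, or 1 and 1 over the list alone (median -0.57, mean -0.21, camera up, adjusted p = 0.00594; adjusted p = 0.429 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 1.48, and Junb fell by 0.93 as deposited, with -0.10 after scaling (limma adjusted p = 0.757).

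The other 4 lists that camera ranked up had no member or only falling members past the test. None of 11 cell cycle genes passed, also adjusted over the list alone (median -0.19, mean -0.16, camera adjusted p = 0.00103; adjusted p = 0.418 with an estimated correlation), with Ccna2 at -0.35 and Cdc20 at -0.46. None of 9 glucocorticoid-responsive genes passed, also over the list alone (median -0.13, mean -0.21, camera adjusted p = 0.00200; adjusted p = 0.429 with an estimated correlation; call lost with quantile normalization), with the metallothioneins Mt2 at -0.88 and Mt1 at -0.53. Of 8 endothelial genes 2 fell and 0 over the list alone (median -0.18, mean -0.34, camera adjusted p = 0.0277; adjusted p = 0.611 with an estimated correlation). That call was lost after scaling (median 0.61, camera adjusted p = 0.0762), with quantile normalization, and without control 2 or 3 or OVA 1 or 2 (camera adjusted p = 0.0622, 0.0601, 0.0706 and 0.108). Kdr, a receptor of vascular endothelial growth factor, fell by 0.96 and Ednrb, an endothelin receptor, by 1.09, and neither passed after scaling (limma adjusted p = 0.687 and 0.512). Ednrb also lost its call without control 1, 3, 4 or 5 or OVA 3, 4 or 5 (limma adjusted p = 0.0666, 0.0638, 0.0517, 0.0604, 0.0575, 0.0893 and 0.0841). None of 6 skeletal muscle genes passed, also over the list alone (median 0.18, mean -0.14, camera adjusted p = 0.00266; adjusted p = 0.429 with an estimated correlation), with Tnnt3 at -1.37 and Ckm at -0.32. That call was lost after scaling (camera adjusted p = 0.493), with quantile normalization, and without OVA 4 (camera adjusted p = 0.157), a library with transcripts of other organs.

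Camera did not call the other 20 lists. In 14 of them it ranked the list up while median and mean were below 0. These were mast cells and basophils (2 of 4 genes fell, median -0.69, camera adjusted p = 0.578), T cells (0 of 3, -0.22, 0.199), neutrophils (1 of 4 fell, -1.40, 0.649), the NF-kappaB pathway (3 of 14 fell, -0.42, 0.0714), interferon-stimulated genes (3 of 11 fell, -0.64, 0.262), MHC class II (1 of 8 fell, -0.78, 0.199), dendritic cells (2 of 6 fell, -0.25, 0.178) and monocytes with interstitial macrophages (1 of 8 fell, -0.55, 0.0692). They also held leukotriene and prostaglandin genes (1 of 5 fell, -0.66, 0.955), extracellular matrix (1 of 13 rose and 7 fell, -1.22, 0.649), alveolar type 2 cells (2 of 10 fell, -0.89, 0.352), alveolar type 1 cells (2 of 8 fell, -0.59, 0.398), adipose tissue (0 of 3, -1.13, 0.352) and mesothelium (0 of 4, -0.52, 0.279). The other 6 were ranked down, of which Nrf2 and the clock are given above. The remaining 4 were the germinal centre (2 of 3 fell, -1.39, 0.570), aryl hydrocarbon receptor targets (1 of 3 fell, -0.74, 0.836), heat shock (5 of 7 fell, -1.05, 0.548) and cardiac muscle (4 of 8 fell, -1.57, 0.199). Adjusted over the list alone the counts were the same except for neutrophils (0), NF-kappaB (1), interferon (2), extracellular matrix (1 and 8) and cardiac muscle (5). Camera called cardiac muscle after scaling (adjusted p = 0.0475) and with quantile normalization. It called interferon (adjusted p = 0.0454) and cardiac muscle (0.0310) without control 5, mesothelium (0.0363) without OVA 1, and NF-kappaB (0.0444) and monocytes (0.0280) without OVA 5.

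Of the 6 lists with fewer than 3 tested genes, squamous epithelium and sex had 0 tested. Log2 changes in OVA against control, OVA_Rg3 against OVA and OVA_Rg3 against control were -2.11, 1.60 and -0.51 for Ear1 and -0.37, 1.66 and 1.29 for Ear2, both of eosinophils. They were -0.09, 0.07 and -0.01 for Gata3 and 0.11, -0.08 and 0.02 for Pdcd1, of T helper 2 and regulatory T cells. Gzma of natural killer cells had -0.99, 1.27 and 0.28, and Cd1d1 of the thymus list had -0.27, 0.75 and 0.48. None of the 18 passed (limma adjusted p from 0.0709 for Ear1 in OVA against control), and Gata3 changed sign and was called higher with quantile normalization in OVA against control (0.70, limma adjusted p = 0.0257).

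Some fixed genes of allergic inflammation were not tested. Il4, Il5, Il13, Ifng, Il17a and Il6 were not in the deposited table, and Muc5ac and Tnf stayed under the filter, with Muc5ac at 0.932 ± 0.863 (SD, n = 5) in control and 0.464 ± 0.418 (SD, n = 5) in OVA. Retnla, a product of alternatively activated macrophages, was 4034 ± 3487 (SD, n = 5) in OVA and 1988 ± 1343 (SD, n = 5) in control (log2 change 0.86, limma adjusted p = 0.226). Il33, an epithelial alarmin, changed by 0.57 (limma adjusted p = 0.236), and the eotaxins Ccl11 and Ccl24 by 0.44 (0.291) and 0.66 (0.159). These did not pass, but after scaling Il33, Ccl11 and Ccl24 rose by 1.35, 1.21 and 1.09. Ccl24 ranged from 0 to 1.32 in control and from 0.907 to 2.74 in OVA. Il1b had a change of -0.10 (limma adjusted p = 0.873).

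The comparison of OVA_Rg3 with OVA asks what Rg3 changed in allergic lungs. Acta2 of smooth muscle and Dbp of the clock were among the genes with the smallest p, though neither passed. Acta2 was 71.1 ± 27.1 (SD, n = 5) in OVA_Rg3 and 21.1 ± 3.24 (SD, n = 5) in OVA, and Dbp was 32.2 ± 12.3 (SD, n = 5) against 7.76 ± 3.56 (SD, n = 5). None of the fixed genes of allergic inflammation passed. Means ± SD (n = 5) of OVA_Rg3 and OVA were 504 ± 439 and 563 ± 638 for Chil3. They were 116 ± 107 and 88.6 ± 69.0 for Clca1 and 14.9 ± 10.9 and 23.4 ± 23.4 for Arg1.

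With limma 0 genes rose and 0 fell, with 1756 genes at an unadjusted p under 0.05, of which 1723 were higher and 33 lower. After scaling 0 genes passed, with 1045 at an unadjusted p under 0.05, 515 higher and 530 lower. Quantile normalization gave 0, the filter at 5 gave 2 (Acta2 and Dbp, adjusted p = 0.0373 each), and a pseudocount of 0.1 gave 1 (Mfsd6, adjusted p = 0.0360). Array weights gave 6979, 6947 of them higher. As deposited (median log2 change 0.32), the groups did not overlap for 255 genes higher and 1 lower, 2.11%, against 0.794% by chance. Without control 2, 3 genes passed (Acta2, Dbp and Slurp2), without OVA_Rg3 1, 3 passed (Acta2, Nanp and Dbp), without OVA_Rg3 5, 2 passed (Acta2 and Mfsd6), and without OVA 5, 1 passed (Dbp). Without the 3 libraries 2 passed, Nanp by 2.45 and Dbp by 2.23, and with scaling as well 1 passed, Nanp by 2.49. After scaling 1 gene passed without OVA_Rg3 5. Nanp and Slurp2 were chosen after their values were seen. Nanp was listed at 0 in 4 of the 5 OVA libraries and in OVA_Rg3 1, and Slurp2 was listed at 0 in all 5 OVA libraries.

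Acta2 had a log2 change of 1.62 ± 0.26 (SE, n = 5 per group) and Dbp one of 1.93 ± 0.32 (SE), each with limma adjusted p = 0.0624. Mfsd6, a membrane transporter of the major facilitator family, had 1.41 ± 0.24 (SE, limma adjusted p = 0.0743). Acsf2, an acyl-CoA synthetase, had 1.34 ± 0.26 (SE), and Mapk14, the p38 kinase, had 1.81 ± 0.35 (SE), both with limma adjusted p = 0.143. In each of the 5 all OVA_Rg3 libraries lay above all OVA libraries. After scaling the changes were 1.21, 1.53, 1.25, 1.02 and 1.54, with limma adjusted p from 0.0824 (Mfsd6) to 0.351 (Dbp).

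Camera ranked 1 list up and 7 down, against other genes whose median was 0.32, and with an estimated correlation 0 lists passed. After scaling it ranked 4 up and 7 down, with quantile normalization 7 up and 5 down, and without the 3 libraries with transcripts of other organs 4 up and 8 down. The smooth muscle list was up, with 0 of 8 genes past the test and 5 adjusted over the list alone (median 0.89, camera adjusted p = 1.18e-05; adjusted p = 0.555 with an estimated correlation). Actg2 had a log2 change of 1.55. The erythroid list was down, with 0 of 6 genes past the test and 4 lower over the list alone (median -0.85, camera adjusted p = 3.61e-13; adjusted p = 0.196 with an estimated correlation). Hbb-bs and Alas2, the first enzyme of haem synthesis in red cells, had -0.85 and -1.17. The mitochondrial list was down with 0 of 9 genes past the test (median -0.25, camera adjusted p = 1.11e-06; adjusted p = 0.555 with an estimated correlation), with mt-Co2 at -0.50 and mt-Co3 at -0.54. Quantile normalization, which holds down changes of the most abundant genes, gave it a median of 0.00 (camera adjusted p = 0.851).

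The B cell list was down with 0 of 6 genes past the test (median -0.31, camera adjusted p = 0.000204; adjusted p = 0.555 with an estimated correlation), with Pax5 at -0.64 and Cd79b at -1.12. Cd79b ranged from 0 to 22.0 in OVA_Rg3 and from 5.53 to 24.8 in OVA. The plasma cell list was down with 0 of 8 (median -0.30, camera adjusted p = 0.000687; adjusted p = 0.566 with an estimated correlation; call lost with quantile normalization), with Mzb1, a chaperone of antibody assembly, at -1.44 and Sdc1 at 0.68. Mzb1 ranged from 0 to 35.8 in OVA_Rg3 and from 13.1 to 51.5 in OVA. The proinflammatory list was down with 0 of 8, or 1 lower over the list alone (median -0.07, camera adjusted p = 0.00385; adjusted p = 0.555 with an estimated correlation), and the call was lost after scaling (adjusted p = 0.0677) and with quantile normalization. Ccl3, which ranged from 0 to 2.58 in OVA_Rg3 and from 1.08 to 7.18 in OVA, had -1.52, and Ptgs2 had 0.60. The cell cycle list was down with 0 of 11 (median -0.05, camera adjusted p = 0.000876; adjusted p = 0.566 with an estimated correlation). Ccnb2, a cyclin, had -0.49, with 0 to 3.04 in OVA_Rg3 and 1.03 to 3.65 in OVA, and Top2a, a topoisomerase, had -0.29. The NF-kappaB list had a median of 0.12 and a mean of 0.04, while camera ranked it down with 0 of 14 past the test (adjusted p = 0.0383; adjusted p = 0.736 with an estimated correlation). Nfkbia, the inhibitor of NF-kappaB, had -0.75 and Rel had 0.41. That call was lost without OVA 1 or OVA_Rg3 1 or 3 (camera adjusted p = 0.0787, 0.145 and 0.0892) and without the 3 libraries (0.181). With scaling and without the 3 libraries the calls of the mitochondrial, plasma cell, proinflammatory and NF-kappaB lists were lost (camera adjusted p = 0.144, 0.152, 0.152 and 0.257). In each of these lists, no other member passed adjusted over the list alone.

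The circadian list was not called (median 0.75, camera adjusted p = 0.0573), with 0 of 14 past the test and 5 higher adjusted over the list alone. Its camera call was gained after scaling (adjusted p = 0.0349), with quantile normalization, without the 3 libraries (0.0473), and without control 3, 4 or 5, OVA 2, 3 or 5, or OVA_Rg3 1, 2 or 4 (camera adjusted p = 0.0489, 0.0179, 0.0102, 0.0187, 0.0363, 0.0359, 0.0171, 0.00746 and 0.0459). With an estimated correlation it was not called (adjusted p = 0.736, and 0.174 after scaling). Of the list means, 0 of 37 passed the exact permutation test after adjustment, with the smallest p at 0.0159 for smooth muscle (adjusted p = 0.440), where 4 of 5 OVA_Rg3 libraries lay above all OVA libraries. Camera called 13 lists without OVA 1, 16 without OVA 2, 15 without OVA_Rg3 1 and 13 without OVA_Rg3 2, against 8 with all libraries. The ciliated list changed direction without OVA_Rg3 1, from camera down with a median of 0.29 (adjusted p = 0.720) to up with a median of 0.73 (adjusted p = 0.0168).

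Of the other 27 lists camera called 0, with adjusted p from 0.0613 (interferon-stimulated genes) to 0.926 (heat shock). It ranked 16 of them down while median and mean were above 0, and 3 down (type 2 cytokines, T cells and mesothelium) with a median below and a mean above 0. After scaling calls were gained by extracellular matrix, alveolar type 1 cells and immediate early genes (camera adjusted p = 0.0420, 0.0436 and 0.0420), and with quantile normalization by these and by alveolar type 2 cells, club cells and endothelium. Without the 3 libraries they were gained by alveolar type 1 cells, club cells, immediate early genes and glucocorticoid response (from 0.00434 to 0.0457). Calls were also gained without single libraries, with adjusted p from 8.15e-05 to 0.0490. They were gained by the mucous list without OVA 1 or 4 or OVA_Rg3 3 or 5, interferon without OVA 1 or 2 or OVA_Rg3 2 or 5, mesothelium without OVA 1 or 2 or OVA_Rg3 4, and skeletal muscle without OVA 1 or 2 or OVA_Rg3 1. The same held for immediate early genes without OVA 3 or OVA_Rg3 1 or 2, club cells without OVA 2 or OVA_Rg3 1 or 2, type 2 cytokines without OVA 2 or OVA_Rg3 2, and alveolar type 1 cells without OVA 2 or OVA_Rg3 1. It also held for alveolar type 2 cells and cardiac muscle without OVA 1, endothelium without OVA 2, glucocorticoid response and adipose tissue without OVA_Rg3 1, and extracellular matrix without OVA_Rg3 5. Over the list alone 2 leukotriene, 3 extracellular matrix, 2 alveolar type 1 and 1 club cell gene were higher, and 1 alveolar macrophage gene was lower.

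The fixed genes did not pass in OVA_Rg3 against OVA. Chil3 had a log2 change of 0.22, Retnla 0.11, Clca1 0.56, Arg1 -0.56, Ccl11 0.68, Ccl24 -0.23, Il33 -0.07 and Il1b -0.23, with limma adjusted p from 0.359 (Ccl11) to 0.940 (Il33). Ccl24 and Il1b were listed at 0 in OVA_Rg3 1, and Il1b in OVA_Rg3 5 as well. Chil3, Retnla and Ccl11 had -0.20, -0.31 and 0.29 after scaling, so the first 2 changed sign.

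Genes changed by OVA and changed back by Rg3 were counted as 0 of 12137 with limma, since 0 genes passed in OVA_Rg3 against OVA (1756 at an unadjusted p under 0.05). Both comparisons share the OVA libraries, and groups simulated without any change gave a median of 0 and at most 0. The count was 2 with the filter at 5, 6596 with array weights, 1 with a pseudocount of 0.1, 2 without the 3 libraries with transcripts of other organs and 1 with scaling as well. It was 3 without control 2 or OVA_Rg3 1, 2 without OVA_Rg3 5 and 1 without OVA 5. The covariance of the log2 changes was -0.0816, and simulated groups gave -0.0496, ranging from -0.219 to 0.0339.

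**Figure D4:**
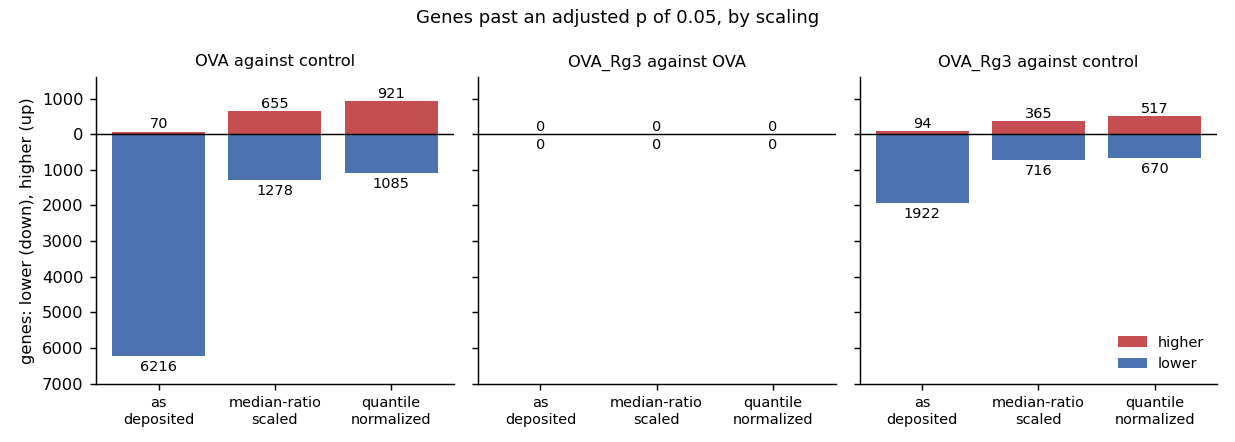
Numbers of genes called higher and lower by limma in the 3 comparisons (y axis, genes), as deposited, after quantile normalization and after median-ratio scaling. Bars are counts of the 12137 genes tested. In OVA against control 6216 genes are lower as deposited and 1278 after median-ratio scaling.

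The comparison of OVA_Rg3 with control asks what remained different from normal lung under Rg3. Chil3 and Clca1 were higher than in control. Chil3 was 504 ± 439 (SD, n = 5) against 32.4 ± 11.3 (SD, n = 5), and Clca1 was 116 ± 107 (SD, n = 5) against 16.0 ± 20.7 (SD, n = 5). Most genes of club and ciliated cells were lower as deposited, with Cyp2f2 at 826 ± 471 (SD, n = 5) against 2861 ± 752 (SD, n = 5) and Foxj1 at 34.0 ± 17.0 (SD, n = 5) against 150 ± 53.3 (SD, n = 5). Acta2 was 71.1 ± 27.1 (SD, n = 5) against 204 ± 44.0 (SD, n = 5).

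With limma 94 genes rose and 1922 fell, 95.3% of the calls lower, and after scaling 365 rose and 716 fell, or 66.2% lower. Quantile normalization gave 517 higher and 670 lower, array weights gave 7369 genes, the filter at 5 gave 1197 and a pseudocount of 0.1 gave 959. As deposited (median log2 change -0.43), the groups did not overlap for 67 genes higher and 2245 lower, 19.0%, against 0.794% by chance. Without the 3 libraries 148 rose and 2197 fell, and with scaling as well 530 rose and 577 fell, or 52.1% lower. The count was 1152 without control 1, 1063 without control 3, 1113 without control 4 and 1132 without OVA_Rg3 5. After scaling it was 446, 224 and 324 without control 1, 3 and 4, and 577 and 444 without OVA_Rg3 2 and 5.

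Of the calls against control, 36 genes rose and 1881 fell in both OVA and OVA_Rg3. Independent lists of these lengths would share 0.542 and 984, and simulated unchanged groups shared at most 1. With the controls split 2 and 3 between the comparisons, the medians over 20 splits were 11 shared higher (at most 16) and 485 shared lower (2 to 850). After scaling 265 rose and 589 fell in both, against 19.7 and 75.4 for independent lists, and split controls gave 22.5 (at most 58) and 29 (0 to 87). The covariance of the log2 changes was 0.294, or 0.251 with split controls, against 0.0579 in simulated groups.

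Chil3 rose by 3.60 ± 0.65 (SE, n = 5 per group; limma adjusted p = 0.00285) and Rnase2a by 3.44 ± 0.53 (SE, limma adjusted p = 0.00165). Rprml rose by 1.74, Krt80, a keratin, by 1.54, Cyp26b1, which degrades retinoic acid, by 1.51 and Prx, periaxin, by 1.51. Aes rose by 1.43, mt-Co1 by 1.38, mt-Co2 by 1.38 and Stac2 by 1.38. All 10 rose after scaling, by 1.45 (Stac2) to 4.03 (Chil3). Stac2 ranged from 0 to 0.546 in control and from 1.49 to 3.64 in OVA_Rg3. Prx lost its call without control 3 (limma adjusted p = 0.0546), and mt-Co1 and mt-Co2 lost theirs with quantile normalization (limma adjusted p = 0.0768 and 0.690). That method holds down changes of the most abundant genes.

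Among the falls, Pon1 fell by 2.79 ± 0.30 (SE, limma adjusted p = 0.000193) and Itih2, a hyaluronan-binding protein, fell by 2.69 ± 0.29 (SE, limma adjusted p = 0.000193). Scgb1c1 fell by 3.52, Fam183b, a ciliary protein, by 3.12, Sult1d1 by 3.10 and Cnn1 by 3.03. Lhb fell by 2.95, Prob1 by 2.93, Aldh3a1, an aldehyde dehydrogenase, by 2.77 and Riiad1 by 2.70. Scgb1c1, Fam183b, Cnn1, Lhb, Aldh3a1, Riiad1 and Itih2 were listed at 0 in OVA_Rg3 1, with highest OVA_Rg3 values of 18.7, 142, 23.5, 6.55, 11.9, 25.1 and 1.85 and lowest control values of 44.4, 146, 39.0, 16.3, 19.7, 39.3 and 5.50. Fam183b lost its call without control 1, 3, 4 or 5 or OVA_Rg3 5 (limma adjusted p = 0.0886, 0.0920, 0.0803, 0.0722 and 0.0615) and after scaling (0.109). Aldh3a1 lost its call after scaling (limma adjusted p = 0.0630).

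Of 8 smooth muscle genes 7 fell, also adjusted over the list alone and after scaling (median -1.65, camera adjusted p = 3.74e-05; adjusted p = 0.567 with an estimated correlation). Des, desmin, fell by 1.75, Tagln, transgelin, by 1.43, and Acta2 by 1.58. Of 9 ciliated genes 8 fell, or 9 adjusted over the list alone, and 6 fell after scaling (median -2.19, camera adjusted p = 3.74e-05; adjusted p = 0.567 with an estimated correlation). Foxj1 fell by 2.19 and Tppp3 by 1.63. Of 7 club cell genes 5 fell, or 6 over the list alone, and 1 fell after scaling (median -1.30, camera adjusted p = 0.00868; adjusted p = 0.567 with an estimated correlation). Scgb3a2, a secretoglobin, fell by 2.35 and Cyp2f2 by 1.95. Without the 3 libraries with transcripts of other organs the camera call of the club list was lost.

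All 9 mitochondrially encoded genes rose, also over the list alone and after scaling (median 1.29, camera adjusted p = 2.97e-23; adjusted p = 0.0559 with an estimated correlation; call lost with quantile normalization), with mt-Nd5 rising by 1.37. The list means of smooth muscle, club cells, ciliated cells, mitochondrial transcripts, Nrf2 and the germinal centre passed the exact permutation test (two-sided, p = 0.00794, adjusted p = 0.0489), with all 5 OVA_Rg3 libraries beyond all 5 controls. After median-ratio scaling alveolar macrophages (difference 0.52) and endothelium (0.80) passed in place of club cells and Nrf2 (adjusted p = 0.176 for both). As deposited, none passed without any 1 of controls 1 to 4 or of the 5 OVA_Rg3 libraries. Of 7 Nrf2 genes 2 fell, or 4 over the list alone (median -0.95, camera adjusted p = 0.312), with Nqo1 falling by 1.48 and Osgin1 by 1.46. Osgin1 lost its call without control 1, 3 or 5 (limma adjusted p = 0.0614, 0.0599 and 0.0558). Of 3 germinal centre genes 2 fell, also over the list alone (median -1.24, camera adjusted p = 0.346). Cxcl13, a B cell chemokine, fell by 2.05 and Bcl6, a germinal centre regulator, by 1.24. Cxcl13 lost its call without control 3, 4 or 5 or OVA_Rg3 4 or 5 (limma adjusted p = 0.0913, 0.0571, 0.0776, 0.0638 and 0.0856). Bcl6 lost its call without control 1, 3, 4 or 5, OVA 3, or OVA_Rg3 1, 4 or 5 (limma adjusted p from 0.0521 to 0.106).

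Camera ranked 10 further lists up against other genes, whose median was -0.43, and in all 10 the call was lost with an estimated correlation. After scaling camera called 4 lists up and 3 down in all, and with quantile normalization 3 up and 4 down. Of the 10 lists, type 2 cytokines, endothelium and erythroid genes kept their call after scaling (camera adjusted p = 0.0414, 0.00128 and 0.00361), and the other 7 lost it (from 0.0578 to 0.318) and lost it with quantile normalization as well. For the first 5 below adjusted p = 0.567 with an estimated correlation. Of 10 genes of alternatively activated macrophages 2 rose and 1 fell, or 3 and 3 over the list alone (median 0.45, camera adjusted p = 0.00222). Fcrls, an immune receptor of macrophages, fell by 1.05, from 1.37 to 2.99 in control to 0 to 1.24 in OVA_Rg3, and lost its call after scaling (limma adjusted p = 0.0607). Of 8 type 2 cytokine and chemokine genes 1 rose, also over the list alone (median 0.39, camera adjusted p = 0.00252). Ccl11, eotaxin, rose by 1.12 and lost its call without control 1, 2, 3 or 5 or OVA_Rg3 2 or 3 (limma adjusted p = 0.0993, 0.0622, 0.0766, 0.0630, 0.0633 and 0.0814). Ccl7 had -1.09, with OVA_Rg3 1 at 0. Of 8 plasma cell genes 1 rose, also over the list alone (median 0.16, camera adjusted p = 0.00428). Jchain rose by 2.89 and lost its call without control 1, 4 or 5 or OVA_Rg3 1, 2, 3 or 5 (limma adjusted p from 0.0520 to 0.111), and Sdc1 had -1.16. None of 8 endothelial genes passed, also over the list alone, and 3 rose after scaling (median 0.53, camera adjusted p = 0.000930). Cdh5, the endothelial cadherin, had 0.92 and Tek, a receptor of angiopoietins, 0.88. None of 6 erythroid genes passed, also over the list alone (median 0.44, camera adjusted p = 0.000357), with Hba-a1 at 0.71 and Hbb-bs at 0.48. The alveolar macrophage list had 1 of 7 genes lower, also over the list alone (median 0.50, camera adjusted p = 0.0294; adjusted p = 0.567 with an estimated correlation), with Plet1 falling by 1.60 and Pparg at -0.60. That call was lost without control 2 or 4 or OVA_Rg3 2 or 3 (camera adjusted p = 0.0522, 0.0527, 0.05001 and 0.0571).

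Of 10 mucous genes 1 rose, also over the list alone (median 0.13, camera adjusted p = 0.0147; adjusted p = 0.598 with an estimated correlation). Clca1 rose by 3.37 and lost its call without control 4 or 5 (limma adjusted p = 0.0545 and 0.0542), and Tff2, a trefoil factor, had -2.46, with 0 to 22.3 in OVA_Rg3 and 16.4 to 176 in control. The list's call was lost without control 5 or OVA_Rg3 3 (camera adjusted p = 0.0634 and 0.0972). None of 6 B cell genes passed (median 0.13, camera adjusted p = 0.0154; adjusted p = 0.660 with an estimated correlation), with Cd79a at 0.84, and the call was lost without control 4 or OVA_Rg3 2 or 3 (camera adjusted p = 0.0757, 0.174 and 0.0707). None of 9 glucocorticoid-responsive genes passed (median 0.21, camera adjusted p = 0.0151; adjusted p = 0.660 with an estimated correlation), with Mt2 at -0.44 and Mt1 at -0.41, and the call was lost without control 5 or OVA_Rg3 1 (camera adjusted p = 0.0507 and 0.0812). None of 6 skeletal muscle genes passed (median 0.54, camera adjusted p = 0.0147; adjusted p = 0.660 with an estimated correlation), with Acta1 at 1.13 and Atp2a1 at 0.70. That call was lost without control 5 or OVA_Rg3 1 (camera adjusted p = 0.0577 and 0.681), and without OVA_Rg3 1 the median was -0.62. For the last 3 lists 0 genes passed adjusted over the list alone.

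Camera did not call the other 21 lists, with adjusted p from 0.0579 (MHC class II) to 0.991 (interferon-stimulated genes). Of these lists 14 were ranked up with a median and a mean below 0. Of 14 clock genes 3 fell, or 5 over the list alone (median -0.58, camera adjusted p = 0.751). In extracellular matrix 1 of 13 rose and 3 fell, in cardiac muscle 3 of 8 fell, and in dendritic cells 1 of 6 rose and 1 fell. In mast cells, NF-kappaB, interferon, leukotriene, alveolar type 1, aryl hydrocarbon receptor and heat shock lists 1 gene each fell. Quantile normalization gave a camera call to cardiac muscle, and leaving out a single library gave one to 4 of these lists. MHC class II was called without control 1 or 3 or OVA_Rg3 1, 4 or 5 (adjusted p from 0.0223 to 0.0481), and alveolar type 2 cells without control 1 or 5 or OVA_Rg3 1 or 5 (from 0.0374 to 0.0451). Alveolar type 1 cells were called without control 1 or 5, OVA 1, or OVA_Rg3 1 or 5 (from 0.0206 to 0.0457), and cardiac muscle without control 1 or 5, OVA 2 or OVA_Rg3 5 (from 0.00998 to 0.0498).

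Of the fixed genes, Arg1 rose by 2.58 ± 0.61 (SE, limma adjusted p = 0.00976). Mmp12, of the largest rise with OVA, rose by 2.55 (0.0358) and lost its call without control 1, 3, 4 or 5 or OVA_Rg3 2, 3 or 5 (limma adjusted p from 0.0516 to 0.0840). Retnla had 0.98 (limma adjusted p = 0.248), Il33 0.50 (0.374), Ccl24 0.43 (0.434) and Il1b -0.32 (0.654). Muc5ac, under the filter, was 0.727 ± 0.448 (SD, n = 5) in OVA_Rg3, and Tnf was 0.465 ± 0.529 in control, 0.369 ± 0.385 in OVA and 0.0790 ± 0.177 in OVA_Rg3 (SD, n = 5 each).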

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

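The tests of the mitochondrial share, of the nuclear-encoded genes of the respiratory chain, of the other organs and of the airway lists were chosen after the results were seen, and the test of transcript length was written before. Within each group of 5, the highest or lowest library was set apart where its gap to the nearest other exceeded 71% of the range. Of 900 groups tested 91 values stood apart in this way. Leaving out the sums over organ lists, which were chosen after the values were seen, 76 of 885 did, and chance gives about 1 in 20. Values in brackets below are the range of the other 4 libraries of the group.

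Control 2, OVA 4 and OVA_Rg3 1 held transcripts of other organs, and 15 of the 91 values are their sums over organ lists. The epididymis list summed to 372 in control 2 (0 to 0.482), 194 in OVA 4 (0 to 0.496) and 1353 in OVA_Rg3 1 (0 to 1.49). The liver list summed to 443 (1.02 to 2.06), 219 (0.268 to 5.93) and 1762 (5.63 to 86.9, the highest in OVA_Rg3 5) in the same libraries, and the nervous system list to 92.8 (12.8 to 17.5), 60.2 (5.42 to 8.65) and 482 (10.6 to 17.2). The skeletal muscle list summed to 234 (9.94 to 19.7), 132 (4.65 to 25.2) and 887 (6.59 to 22.8), and the adipose tissue list to 119.7 (2.77 to 9.06), 57.0 (0.0764 to 3.02) and 407 (1.02 to 3.72). Of the genes, 1 of 8, 9 of 10, 3 of 8, 7 of 7 and 2 of 5 reached a value of 1 in another lung library at least once, and 0, 1, 3, 4 and 1 did so in most of them. Gpx5 of epididymis was at 161, 86.4 and 524 in control 2, OVA 4 and OVA_Rg3 1 and at most 1.49 elsewhere, Alb of liver at 178, 92.4 and 716 and at most 31.0, and Gap43 of the nervous system at 13.8, 14.996 and 104 and at most 9.51. Acta1 of skeletal muscle was at 79.2, 38.1 and 310.5 and at most 5.75, and Adipoq of fat at 33.4, 17.7 and 129 and at most 4.14. OVA_Rg3 5 also held liver transcripts, with 9 of 10 liver genes at 1 or more (Alb at 31.0) and the epididymis list at 0, and it stayed in the fits without the 3 libraries.

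The ratios of the organ lists to the epididymis list differed by at most 1.43-fold between the 3 libraries, which is consistent with 1 mixture of organs reaching all 3. Reads spread alike to all libraries are argued against, since the highest other library had 1.09% of the epididymis reads per kb of the lowest of the 3. The same share of each library is argued against as well, since the summed epididymis values differed by 6.97-fold, while reads per kb differed by 2.41-fold and implied depth by 16.8-fold. The step at which the mixture entered stays open. No biological explanation was tested, since the design gives none for these 3 libraries.

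Genes called lower far outnumbered genes called higher in OVA against control (98.9% lower). A larger share of mitochondrial transcripts may account for much of this. With every library set to the same sum over the genes not encoded in mitochondria, the median log2 change of 12124 of them went from -0.73 to 0.0121 (-0.11 to 0.08 without single libraries). Other abundant genes taking the share would have left that median away from 0, but an equal fall of all nuclear transcripts would give the same value, so the 2 cannot be separated by it. More mitochondria with their nuclear-encoded parts are argued against, because 28 nuclear-encoded genes of oxidative phosphorylation had a median scaled log2 change of -0.0435 (quartiles -0.17 to 0.10), against 2.44 for the mitochondrial list. Loss of long transcripts from degraded RNA stays open, with a Spearman rho of -0.0574 between transcript length and scaled log2 change over 12132 genes (-0.08 to -0.04 without single libraries), and genes are not independent replicates. An effect of OVA itself on the mitochondrial share is open and untested, since treatment and share go together in all 5 OVA libraries.

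Club, ciliated and smooth muscle genes were lower in OVA than in control. Scaling between libraries is argued against as the whole cause, since the list nearest to 0 had a median of -1.22 over median-ratio scaling and quantile normalization, with all 3 lists called by camera, although the mean of the club list did not pass the exact test after scaling (adjusted p = 0.0801). The libraries with transcripts of other organs are argued against too, since the value nearest to 0 was -1.12 with scaling and without them. Less airway in the piece of lung sampled cannot be told apart from an effect of OVA, because the mucous list, at a scaled median of 0.40, is itself a target of OVA. With an estimated correlation none of the 3 lists was called, and an effect of OVA stays among the open explanations.

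The remaining values follow, and their causes were not tested. Acta1, Mylpf, Myh4, Atp2a1, Ckm, Adipoq and Cidec, of the organ lists, go with the mixture in the 3 libraries. Fabp1, Arg1, Slc7a2 and Foxa3, high in some of them, may too. Each value below stood apart from the other 4 libraries of its group. In control 2 this held for the scaling factor at 1.12 (1.41 to 1.48), the MHC class II list at 3.78 (4.48 to 4.63), the dendritic cells list at 1.14 (1.64 to 1.77), the aryl hydrocarbon receptor targets list at 2.19 (2.95 to 3.15) and the skeletal muscle list at 5.14 (1.14 to 1.73). Control 2 also had Mmp12 at 3.53 (0.434 to 0.873), Arg1 at 7.00 (0.324 to 0.876), Rnase2a at 3.47 (0.162 to 0.652), Lat at 6.46 (1.99 to 2.71) and Sdc1 at 30.2 (47.6 to 56.3). Further values of control 2 were Ptgs2 at 6.28 (9.61 to 9.85), H2-DMa at 6.76 (14.3 to 18.002), Lta4h at 2.76 (5.54 to 6.42), Gclc at 22.7 (38.1 to 44.7) and Mylpf at 41.2 (1.86 to 2.49). The same library, control 2, had Myh4 at 25.2 (0.106 to 0.646), Cd1d1 at 6.68 (1.18 to 1.58), Slc7a2 at 4.42 (1.05 to 1.54), Fabp1 at 91.1 (2.10 to 6.35) and Acta1 at 79.2 (0.462 to 1.88). Of control 2, others were Atp2a1 at 20.7 (0.0646 to 0.712), Nfkbib at 4.80 (10.6 to 13.0) and Cd86 at 0 (1.99 to 2.57). In OVA_Rg3 1 this held for the neutrophils list at 1.49 (3.99 to 4.59), the aryl hydrocarbon receptor targets list at 0.53 (2.09 to 2.64), the skeletal muscle list at 7.02 (1.02 to 1.99), the adipose tissue list at 7.05 (0.41 to 1.22) and Retnlg at 0 (10.1 to 26.8). OVA_Rg3 1 also had S100a9 at 0 (22.7 to 36.4), Usp18 at 0 (4.27 to 6.59), Osgin1 at 0 (3.18 to 4.99), Cyp1a1 at 0 (3.72 to 7.16) and Ckm at 83.1 (0.882 to 2.57). Further values of OVA_Rg3 1 were Mylpf at 132 (1.42 to 4.21), Myh4 at 87.1 (0.257 to 1.36), Cfd at 195 (0.282 to 1.36), Cidec at 90.9 (0.457 to 2.65) and Adipoq at 129 (0 to 0.634). The same library, OVA_Rg3 1, had Foxa3 at 12.4 (0 to 0.967), Gsta3 at 6.26 (22.3 to 26.8), Acta1 at 310.5 (1.34 to 5.75), Atp2a1 at 86.2 (0.162 to 2.09) and Fam183b at 0 (56.8 to 142). Of OVA_Rg3 1, others were Nfkbib at 2.14 (5.90 to 8.09). OVA 4 had Adipoq at 17.7 (0 to 0.646), Wt1 at 1.96 (0.488 to 0.714), Fabp1 at 44.8 (0 to 1.72) and Acta1 at 38.1 (1.03 to 3.26).

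In the other libraries fewer values stood apart. Control 1 had Ifit2 at 0.209 (3.48 to 5.98). Control 3 had the plasma cells list at 3.93 (2.38 to 2.82), Tnfrsf17 at 2.63 (0 to 0.304), Mzb1 at 57.1 (4.01 to 8.93) and Prx at 4.95 (7.17 to 8.30). Control 4 had Junb at 17.3 (26.0 to 28.2). In control 5 this held for the immediate early genes list at 4.17 (3.46 to 3.63), Ccl7 at 18.2 (1.28 to 3.16), Oas1a at 13.2 (5.76 to 7.30), Atf3 at 7.97 (2.00 to 3.00) and Srxn1 at 0.1597 (6.80 to 10.4). Control 5 also had Clec10a at 2.20 (1.36 to 1.55). OVA 1 had Slc25a36 at 8.44 (0.109 to 0.719), Rel at 2.08 (0.592 to 0.867), Stac2 at 7.00 (1.75 to 2.59) and Itih2 at 0 (0.671 to 0.840). OVA 2 had Aes at 15.9 (33.7 to 37.4). OVA 3 had Mapk14 at 3.21 (0.669 to 1.14) and Txnrd1 at 3.41 (0.801 to 1.27). OVA 5 had Cnn1 at 1.31 (5.04 to 7.82) and Ccl7 at 0 (1.67 to 2.10). OVA_Rg3 2 had the MHC class II list at 5.57 (3.88 to 4.33), H2-Eb1 at 235 (57.6 to 86.0), Il1a at 6.80 (2.34 to 3.12) and Akap5 at 10.4 (20.5 to 26.1). OVA_Rg3 3 had Muc5b at 18.4 (4.09 to 6.20) and Cfap126 at 48.8 (18.6 to 23.9). OVA_Rg3 5 had Slc25a36 at 0.262 (6.03 to 10.6).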

How the results depend on the processing

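Median-ratio scaling, leaving out the 3 libraries with transcripts of other organs, and both together were chosen after seeing the data, and the other alternatives were fixed before the data were examined. Shares of mitochondrial and Scgb1a1 transcripts kept their side of the threshold in all 16 alternatives, with mitochondrial differences between OVA and control of 36.4 to 45.1 percentage points. The Scgb1a1 difference between OVA_Rg3 and OVA, not past the threshold, changed sign (-0.694 to 2.03 percentage points).

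In OVA against control 6286 genes were called. The count was 2006 with quantile normalization, 3836 with the filter at 5 (which tests fewer genes), 10020 with array weights and 3376 with a minimum log2 change of 1 (a stricter test). It was 1933 with median-ratio scaling and 2553 with scaling and without the 3 libraries. In OVA_Rg3 against control 2016 genes were called, with 1187 under quantile normalization, 1197 with the filter at 5, 7369 with array weights, 959 with a pseudocount of 0.1, 1081 with scaling and 1107 with scaling and without the 3 libraries. In OVA_Rg3 against OVA 0 genes were called with limma (1756 at an unadjusted p under 0.05), with 2 at the filter of 5, 6979 with array weights, 1 with a pseudocount of 0.1, 2 without the 3 libraries and 1 with scaling as well. Array weights ranged from 0.143 (OVA_Rg3 1) to 5.46 (OVA_Rg3 3). Genes changed by OVA and changed back by Rg3 numbered 0, with 2 at the filter of 5, 6596 with array weights, 1 with a pseudocount of 0.1, 2 without the 3 libraries and 1 with scaling as well. Beyond the filter, the threshold and the libraries left out, the cause was not tested.

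Without single libraries the counts ranged from 4412 to 7447 in OVA against control, from 0 to 3 in OVA_Rg3 against OVA, from 1063 to 2574 in OVA_Rg3 against control and from 0 to 3 for genes changed back. Counts moved by over 1.5 times in OVA_Rg3 against OVA and for genes changed back without control 2 (3), OVA 5 (1), OVA_Rg3 1 (3) and OVA_Rg3 5 (2). In OVA_Rg3 against control they did so without control 1 (1152), control 3 (1063), control 4 (1113) and OVA_Rg3 5 (1132). The cause was not tested.

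Camera called 17 lists in OVA against control, with 10 under quantile normalization, 10 with scaling and without the 3 libraries and 2 with an estimated correlation (15 to 19 without single libraries). In OVA_Rg3 against OVA it called 8 (1 up and 7 down), with 12 under quantile normalization (7 up and 5 down), 11 under scaling (4 up and 7 down), 12 without the 3 libraries (4 up and 8 down), 5 under scaling without the 3 libraries and 0 with an estimated correlation (8 to 16, with 13, 16, 15 and 13 without OVA 1, OVA 2, OVA_Rg3 1 and OVA_Rg3 2). In OVA_Rg3 against control it called 14, with 7 under quantile normalization, 7 under scaling, 7 under scaling without the 3 libraries and 0 with an estimated correlation (11 to 18). List means past the exact test numbered 6 in OVA against control, 12 with quantile normalization and 0 without the 3 libraries, scaled or not (0 to 8 without single libraries). They numbered 0 in OVA_Rg3 against OVA (0 to 0), and 6 in OVA_Rg3 against control with 0 without the 3 libraries, scaled or not (0 to 6). With 4 libraries per group the smallest possible p is 0.0286, and 21 of 36 lists would have to reach it to pass, so these 0 counts say little about stability. With all libraries, 6 lists had to reach the smallest p for any to pass, and 6 did in each comparison with control. The 0 counts there without single libraries thus say little about single lists. For the other counts the cause was not tested.

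Some results past the threshold in the analysis as reported or under the alternative took the other direction, which for lists is the direction of camera. In OVA against control quantile normalization gave log2 changes of 0.70 for Gata3, 0.11 for Nfkb2, 0.12 for Oas1a, 0.0406 for Pparg, 0.53 for Lta4h and -0.0515 for mt-Co1. This method holds down changes of the most abundant genes, such as mt-Co1. Median-ratio scaling gave 0.00584 for Nfkb2 and 0.00319 for Oas1a. Scaling without the 3 libraries gave 0.0168 for Nfkb2, 0.00609 for Oas1a, 0.13 for Zfp36 and 0.000320 for Hsp90aa1. In OVA_Rg3 against OVA array weights gave -1.69 for Atp2a1, quantile normalization gave a median of 0.00158 for the mitochondrial list, and the ciliated list had 0.73 without OVA_Rg3 1 (0.0798 to 0.73 without single libraries). Signs also changed below the threshold, as for Chil3 (-0.20) and Retnla (-0.31) with median-ratio scaling in OVA_Rg3 against OVA, and among list medians, as for alternatively activated macrophages in OVA against control (-0.40 to 0.38). The cause was not tested.

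Of 166 named genes in OVA against control, 123 kept direction and side of the threshold with scaling, 33 lost and 8 gained a call. With quantile normalization these numbers were 117, 34 and 9. Of 171 in OVA_Rg3 against control, 142 were the same with scaling, 19 lost and 10 gained a call, and with quantile normalization 138, 21 and 12. Of 158 in OVA_Rg3 against OVA, 158 were the same with either and 81 gained a call with array weights. Over all fits without a single library 2327 of 2475, 2328 of 2335 and 2404 of 2545 results were the same in OVA against control, OVA_Rg3 against OVA and OVA_Rg3 against control. With the replicate number as a block, 161 of 166, 158 of 158 and 162 of 171 were the same. The numbers do not appear to pair the samples, since deviations of libraries of 1 number correlated at -0.389 to 0.328, and 3 of 15 libraries were closest to their own number.

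Depth limits low values most in OVA_Rg3 1, where 3 reads on a transcript of 1 kb make a value of 13.9, and in control 2, where they make 3.62, against 0.334 in control 1.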

Other observations

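The counts of splits for the deposited values, the lists and array weights were planned before the results were seen, and those after median-ratio scaling were chosen after. Libraries of each pair of groups were split 5 against 5 in 100 ways, the real one included. For genes changed in OVA against control 1 of 100 splits gave as many (6286 real, 5590 the highest other). After scaling it was 1 of 100 (1933 and 3). For OVA_Rg3 against control it was 1 of 100 (2016 and 647), and 1 of 100 after scaling (1081 and 2). As 1 of 100 is the lowest possible, chance is unlikely for these 4 counts but not excluded.

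For lists past camera chance cannot be excluded. As many lists were called in 15 of 100 splits for OVA against control (17 real, 24 the highest other), in 47 of 100 for OVA_Rg3 against OVA (8 real, 15 the highest other) and in 12 of 100 for OVA_Rg3 against control (14 real, 18 the highest other).

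In OVA_Rg3 against OVA limma called 0 genes (1756 at an unadjusted p under 0.05). All 100 of 100 splits gave as many, also after scaling (highest other 5518 and 211). Splits that call 5518 genes here and 5590 in OVA against control point to structure of the libraries other than the treatment. With array weights 9 of 100 splits gave as many as the real 6979, with 7878 the highest other, so chance cannot be excluded for that count. In some of these splits, though not the real one, the estimate of the weights stopped before it reached its tolerance. Genes changed by OVA and changed back by Rg3 numbered 0, and all 100 of 100 splits gave as many, with 4862 the highest other.

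Libraries also differed in the number of genes at a value of 1 or more, with 11978 ± 135 (SD, n = 5) in control, 9818 ± 1118 (SD, n = 5) in OVA and 10909 ± 737 (SD, n = 5) in OVA_Rg3. Ddx3y, of the Y chromosome, was at 0.906 in control 2, 0.787 in OVA 4 and 10.2 in OVA_Rg3 1 and at 0 in the other 12 libraries. The former are the 3 libraries with transcripts of other organs, so the mixture and the lung cannot be told apart as its source.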
